A study of Mus musculus with 6 samples.

How the data were processed

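RNA was measured in anterior nasal septum cartilage of 6 mouse embryos at embryonic day 14.5, 3 wild-type (WT) and 3 heterozygous for a point mutation of Fgfr2 that models Apert syndrome (Apert). Per the labels' protocols, heads were frozen, cartilage was laser captured from sections matched for position, and RNA was purified with DNase digestion. Each library was made from 15 ng of total RNA that was first amplified to cDNA with the NuGEN Ovation kit and then fragmented and tagged with Nextera XT, per the labels' protocols. Reads were paired and 100 bp long on an Illumina HiSeq. The series design text describes separate mice of each genotype with 1 sample per mouse, so the spread between libraries includes animals. Amplification from nanogram amounts can distort transcripts by GC content and length and raises the spread of weakly expressed genes. No molecular identifiers were described, so counting limits cover counting error only.

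The deposited files hold whole-number fragment counts per Ensembl gene, which the authors made with featureCounts 1.4.4, per the file headers. Per the file headers, fragments of read pairs were counted over exons, summed per gene and assigned without regard to strand, on Ensembl release 75 gene models of GRCm38. The submitters' processing notes name cutadapt, STAR 2.5.2b and genome build mm10, without the settings used. The header options do not turn on counting of multiply mapped reads. Genes that share exons with another gene, or that have near-identical copies, are therefore uncertain: fragments over shared exons cannot be assigned to 1 gene and fragments of opposite strands cannot be told apart. Coordinates are those of the count files (mm10).

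Each file lists 38924 genes, of which 37607 were matched by identifier to a symbol. The 1317 without a symbol held 0.168% to 0.205% of counts per library and stayed in the library totals, since they are genes. No per-sample column was left unused. Library totals ran from 6760510 to 10834744 counts, so 1 count was 0.148 CPM (counts scaled to a common library total) in the shallowest library. GC content was taken from the longest transcript of each gene in GENCODE M21, and 13192 of the 13333 tested genes had a value.

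Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr kept 13333 genes, libraries were scaled by trimmed mean of M values (TMM), and genotype was tested with the quasi-likelihood F test (glmQLFit, glmQLFTest) and Benjamini-Hochberg adjustment at 0.05. CPM values use TMM-scaled totals unless stated. The standard error of a log2 fold change is its size divided by the square root of F. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01, adjusted over 27 lists, then again with an estimated correlation and with fry. The lists, 28 with the sex-linked genes and 731 genes in all, were written from general knowledge of cartilage, FGF signalling, other cell types of the nose and RNA quality. For 9 symbols of the lists no gene was matched. Shares of counts were compared by two-sided exact permutation tests, whose smallest possible p with 3 against 3 libraries is 0.1. Genes within 10 Mb of Fgfr2 were compared with all others by two-sided Fisher's exact test.

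The grouping, the tests, the lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named Fgfr2, up to 12 called genes with the largest rises and up to 12 with the largest falls with mean CPM of at least 1 and no overlap between groups, and up to 4 members of each list with the smallest p, passing over predicted genes. Only 7 genes fell past the threshold, so all 7 are named, and not every gene that the rule took is named. Smc2, Smc4, Knl1, Spc25, Cntnap2, Ctnnd2, Sema3c, Sema5b, Plxna4, Igf2, Plagl1, Mcm2, Rrm1, Calm2, Hmga2, Kif11, Nusap1, Kif23, Ccnb1, Bub1, Ccnb2, Prc1, Postn, Prrx1, Col1a2, Col12a1 and Gm42418 were named after their values were seen. The same holds for Errfi1, Cic, Ets2 and Dusp6.

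The alternatives set in advance were other scalings, filters and thresholds, the replicate number as a block, and each library left out in turn. They also took in removal of globin, mitochondrial and ribosomal RNA genes, counts thinned to the shallowest total, and removal of X and Y genes. Other tools were DESeq2 1.42.0, limma-voom with and without quality weights, and robust edgeR, and windows of 5 and 20 Mb around Fgfr2 were used. Embryo sex as a covariate was also set in advance. The expression filter was rerun whenever a library was left out, so the genes and list members tested can differ from the full fit. Corrections for GC content and length were added after the data were seen: a smooth curve of each library's log2 deviation on GC content or length was fitted with mgcv 1.9.3 and entered as an offset. Labels do not say that equal replicate numbers mark shared litters or days, and the fit without the block is the one reported.

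The edgeR, DESeq2 and limma-voom calls, camera at its preset correlation and the GC correction were run on simulated data. Counts were drawn for each gene independently from the means, dispersions and totals of these libraries, with 200 of 13333 genes changed (10 runs). The other tests and settings, and correlation between genes, were not simulated. In the comparison of Apert with WT, edgeR found 8.49% of genes changed 1.5-fold, 46.1% of those changed 2-fold and 74.0% of those changed 3-fold, and 5.21% of its calls were unchanged genes. With no gene changed, 0.3 genes were called on average. With a simulated GC trend and a shift of 0.5 (log2) in the cell cycle list, the GC correction gave a list median of 0.51 and called the list in 10 of 10 runs. In these runs edgeR called 23.3 genes on average before the correction and 1 after it. Other lists, which were not shifted, passed camera 1.5 times per run on average before it and 0.2 times after it. Libraries were checked for duplicates: the chi-square per degree of freedom between pairs ran from 11.4 to 50.1, so no pair agreed within sampling noise. Figures were drawn in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.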

Results

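RNA-seq was performed on anterior nasal septum cartilage, the midline cartilage of the nose, captured by laser from frozen sections of embryonic day 14.5 mouse heads. Cartilage of 3 WT mice was compared with that of 3 Apert mice, which are heterozygous for a gain-of-function point mutation in the fibroblast growth factor receptor gene Fgfr2 and model a human craniosynostosis syndrome. The comparison asks which transcripts differ between the genotypes in this cartilage. Total counts were 10834744, 10053237 and 8631181 in WT replicates 1 to 3 and 10527915, 7560437 and 6760510 in Apert replicates 1 to 3 (two-sided exact permutation test, p = 0.3). At least 1 count was found for 18823 ± 128 genes in WT and 18376 ± 143 genes in Apert (SD, n = 3 each; exact permutation p = 0.1, the smallest this design can give). Xist, the X-inactivation transcript of female cells, ran from 9889.9 to 14739 CPM of raw totals, and the Y-linked genes of the sex-linked list had 0 counts in all 6 libraries, which allows up to 3 counts in each. Xist shares exons with its antisense gene Tsix, so its counts may include both.

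Fgfr2 itself was measured at 632 ± 61.9 CPM in WT and 521 ± 59.1 CPM in Apert cartilage (SD, n = 3 each). The log2 fold change was -0.28 with a standard error of 0.14 and did not pass the test (edgeR quasi-likelihood, adjusted p = 0.461; range over all alternatives -0.43 to -0.20). The highest Apert library, at 584 CPM, lay just above the lowest WT library, at 583 CPM. A point mutation leaves the gene's exons in place, so these counts do not check the genotype labels. In the count files Fgfr2 (ENSMUSG00000030849) lies on the minus strand of chromosome 7 from 130162451 to 133123350 (mm10) and shares exons with Ctbp2, so part of its count is uncertain.

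Expression of 60 genes differed between the genotypes, with 53 higher and 7 lower in Apert cartilage. The largest rises included the guidance ligand genes Sema3e (2.92-fold, from 9.21 ± 2.83 to 26.9 ± 3.64 CPM) and Sema3a (2.32-fold, from 29.8 ± 5.64 to 69.3 ± 32.1 CPM; log2 fold change 1.22, and 0.77 without Apert replicate 3) and Lef1, a transcription factor of Wnt signalling (2.65-fold, from 8.62 ± 1.69 to 22.8 ± 6.65 CPM). The DNA glycosylase gene Neil3 rose 2.71-fold, the cohesin acetyltransferase gene Esco2 2.53-fold and Ckap2l, which acts at the mitotic spindle, 2.46-fold. The centromeric cohesin protector genes Sgo2a and Sgo1 rose 2.45-fold and 2.36-fold. Depdc1a, Cip2a and the cytokinesis gene Ect2 increased 2.35-fold, 2.28-fold and 2.28-fold. Of the 7 genes that fell, the matricellular protein gene Smoc2 went from 108 ± 13.6 to 46.6 ± 7.19 CPM, the extracellular matrix gene Emid1 from 25.9 ± 5.83 to 11.4 ± 1.93 CPM, and Nynrin from 33.8 ± 1.66 to 16.2 ± 3.95 CPM. The heparan sulfate proteoglycan gene Sdc4 fell from 91.3 ± 24.4 to 44.7 ± 5.0 CPM and the heparan sulfate polymerase gene Ext2 from 156 ± 34.3 to 87.3 ± 8.80 CPM. Lbh fell from 59.8 ± 8.47 to 29.6 ± 7.36 CPM and the imprinted noncoding RNA H19 from 3278 ± 768 to 1910.5 ± 281 CPM (SD, n = 3 each). On the log2 scale the named changes ran from -1.21 for Smoc2 (standard error 0.17, adjusted p = 0.00453) to 1.55 for Sema3e (standard error 0.26, adjusted p = 0.0122).

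Of 13333 genes tested, 1515 had an unadjusted p below 0.05, where chance gives 667. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 60. In all 60 the 3 Apert libraries lay above or below the 3 WT libraries, as they did in 16.6% of all tested genes, where chance gives 10%. The common biological coefficient of variation was 0.245. When libraries were scaled by their totals alone, 17 genes were higher and 24 lower in Apert. The median log2 fold change of all genes then moved from 0.01 to -0.15, so rises and falls are relative to the scaling. Among the called genes, 11 share exons with another gene and are uncertain. They include Ckap2l with Gm14024, Sgo2a with Kctd18, Nynrin with Gm26751, and H19 with Mir675. Leaving out WT replicate 1, 2 or 3 gave 15, 23 or 0 called genes, and leaving out Apert replicate 1, 2 or 3 gave 229, 2 or 11. Without WT replicate 3, edgeR still gave 1376 genes with an unadjusted p below 0.05. After correction for GC content 5 genes were called: Smoc2, Ckap2l, Sgo1, Mki67 and Ctnnd2. All 60 genes had the same sign after it and an unadjusted p of at most 0.00780, and the median size of their log2 fold changes went from 1.06 to 0.91 (median standard error 0.19 before and after). Calls ended because the folds shrank and because fewer genes had small p values, 1000 below 0.05 in place of 1515, which lowered the largest p that was called from 2.18e-04 to 1.38e-05.

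**Figure D1:**
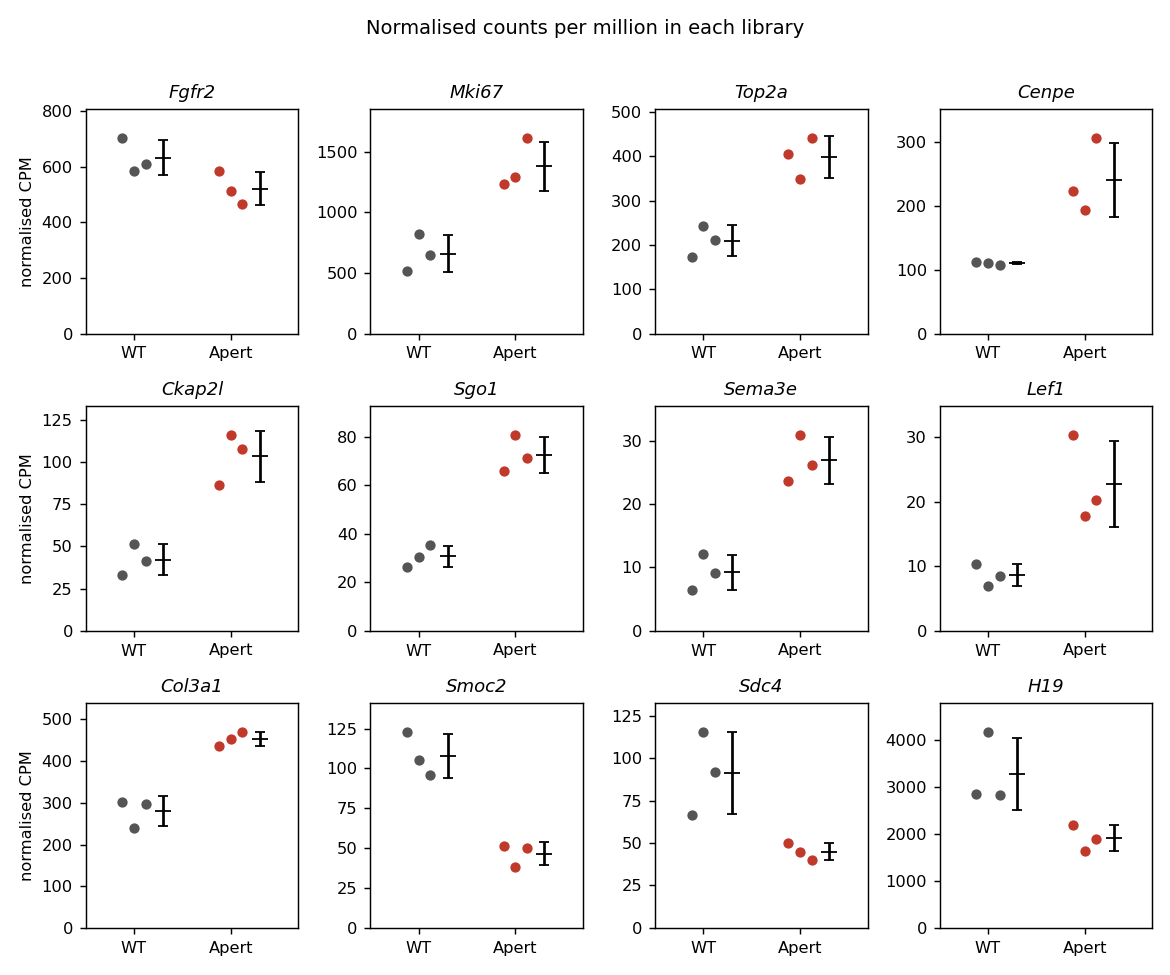
Normalised CPM (y axes, starting at 0) of 12 genes in each library, with WT in grey and Apert in red. Each point is a library and the bar beside each group is its mean ± SD (n = 3). Smoc2, Sdc4 and H19 fell and Mki67, Top2a, Cenpe, Ckap2l, Sgo1, Sema3e, Lef1 and Col3a1 rose with all Apert libraries on the same side of all WT libraries, while Fgfr2 did not pass the test.

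Of the 44 members of the cell cycle list, all measured, 12 rose in Apert cartilage and none fell, while 32 did not pass, of which 7 had negative log2 fold changes. Among those that rose were the proliferation marker Mki67 (661 ± 150.3 to 1379.8 ± 201 CPM), the DNA topoisomerase gene Top2a (209.5 ± 35 to 398 ± 46.9 CPM) and the kinetochore genes Cenpe (111 ± 2.29 to 241 ± 58.4 CPM) and Cenpf (102 ± 10.8 to 211 ± 40.1 CPM; SD, n = 3 each). The others were the mitotic kinesin genes Kif11 and Kif23, the cyclin genes Ccnb1 and Ccnb2, and Nusap1, Ect2, Bub1 and Prc1. Adjusted over the list alone, 21 members rose and none fell. The median log2 fold change was 0.53 (quartiles 0.10 and 0.92), and the list passed the camera test at its preset correlation (adjusted p = 3.08e-11) but not with an estimated correlation (adjusted p = 0.736). Mean expression of the list relative to all libraries was -0.60, 0.06 and -0.24 (log2) in WT replicates 1 to 3 and 0.26, 0.24 and 0.28 in Apert replicates 1 to 3 (exact permutation p = 0.1, the smallest possible). After correction for GC content the median was 0.51 and the list passed at the preset correlation (adjusted p = 2.96e-13) but not with an estimated correlation (0.577), and only Mki67 among its members remained called. The median was 0.34 without WT replicate 1 and 0.79 without WT replicate 2. Signs of RNA quality differed between the same groups: the mitochondrial genome took 29.6% ± 0.756 of counts in WT and 37.1% ± 3.06 in Apert, and fewer genes were detected in each Apert library (SD, n = 3 each; exact permutation p = 0.1 for both). Top2a shares exons with Gm23451 and Nusap1 with Oip5.

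Of 31 perichondrium and fibrous mesenchyme genes 28 were measured, 2 rose and 26 did not pass. Col3a1, a fibrillar collagen of fibrous tissue, rose from 279.9 ± 35.2 to 453 ± 15.8 CPM (adjusted p = 0.0322). Ogn, a small leucine-rich proteoglycan, rose from 86.8 ± 21.8 to 166 ± 31.3 CPM (SD, n = 3 each; adjusted p = 0.0363). Adjusted over the list alone, 9 rose and none fell. Aspn (log2 fold change 1.37, adjusted p = 0.0834) and Tnc (0.61, adjusted p = 0.0914) did not pass. With each library left out in turn their edgeR adjusted p ran from 0.00649 to 0.370 and from 0.0506 to 0.377. The median log2 fold change of the list was 0.20 (camera, adjusted p = 0.0212 at the preset correlation and 0.736 with an estimated correlation). Mean expression of the list relative to all libraries was -0.21, -0.02 and -0.18 (log2) in WT replicates 1 to 3 and 0.09, -0.06 and 0.37 in Apert replicates 1 to 3, so the groups overlap (exact permutation p = 0.2). The median was 0.28 after correction for GC content (adjusted p = 5.88e-04, and 0.577 with an estimated correlation). The list no longer passed without WT replicate 3 (adjusted p = 0.138), Apert replicate 1 (0.0745) or Apert replicate 3 (0.217), and without Apert replicate 3 its median was 0.08.

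The genes of cartilage itself did not pass as a list. List calls in this paragraph are at the preset correlation, and with an estimated correlation in all libraries the cartilage and glycosaminoglycan lists had adjusted p of 0.894 and 0.890. Of 32 cartilage matrix and chondrocyte identity genes 30 were measured and none was called. Adjusted over the list alone 1 rose and 2 fell, and the median log2 fold change was -0.18 (camera, adjusted p = 0.372). Sox9, the master regulator of chondrocytes, was at 762 ± 109 CPM in WT and 479.9 ± 140.3 CPM in Apert (adjusted p = 0.125, with a leave-one-out range of 0.00858, without Apert replicate 1, to 0.400). The chondrocyte matrix gene Chad was at 163 ± 22.2 and 105 ± 3.39 CPM (adjusted p = 0.0695) and the matrilin gene Matn3 at 107 ± 49.9 and 192 ± 39.9 CPM (SD, n = 3 each; adjusted p = 0.197). Without WT replicate 1 the cartilage list passed the test with a median of -0.28 (adjusted p = 0.0266), and without WT replicate 2 its median was 0.00 (adjusted p = 0.987). Among 8 measured members of the osteoblast and bone matrix list none was called, 1 rose adjusted over the list alone, and the median was -0.10 (adjusted p = 0.772). With each library left out in turn this median ran from -0.33 to -0.02. Col1a1 was at 140.4 ± 67.2 and 251 ± 61.3 CPM (adjusted p = 0.165). In the glycosaminoglycan and sulfate synthesis list Ext2 fell, over all genes and adjusted over the list alone, and the other 24 measured members did not pass (median -0.11, adjusted p = 0.261). Without Apert replicate 1 this list passed with a median of -0.27 (adjusted p = 0.0269), and without Apert replicate 3 its median was -0.09 (adjusted p = 0.910). Chondrocyte hypertrophy genes (15 measured, median 0.01, adjusted p = 0.965) and matrix proteases with their inhibitors (25 measured, median -0.04, adjusted p = 0.965) had no member called, over all genes or adjusted over the list alone. Examples were Panx3 (log2 fold change 0.55), Mef2c (-0.27), Timp3 (-0.55) and Adamtsl1 (1.41). With each library left out in turn Panx3 ran from 0.17 to 0.86, Mef2c from -0.38 to -0.21, Timp3 from -0.79 to -0.42 and Adamtsl1 from 0.76 to 1.72. The lowest edgeR adjusted p in these fits was 0.0263 for Timp3 and 0.0258 for Adamtsl1. The 31 measured members of the ER stress and collagen secretion list had none called in either way (median -0.03, adjusted p = 0.772), with the chaperone gene Hsp90b1 at a log2 fold change of 0.47 (adjusted p = 0.169).

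Signalling lists centred on the mutated receptor did not pass. Of 32 FGF/ERK response and feedback genes 22 were measured and none was called, over all genes or adjusted over the list alone (median 0.06, camera adjusted p = 0.375). The median of this list was higher, from 0.11 to 0.21, with each library left out in turn, and 0.20 after GC correction. The expression filter was rerun with each library left out, so those medians can cover other members than the 22. The list did not pass camera in any of these fits. In the fry test it had the lowest unadjusted p of the 27 lists but did not pass after adjustment. The feedback inhibitor genes Spry2 and Spred1 had log2 fold changes of 0.95 (standard error 0.30, adjusted p = 0.206) and 0.43 (standard error 0.15, adjusted p = 0.253). The ERK-induced transcription factor genes Etv5 and Etv1 were at 0.47 (standard error 0.16) and 0.54 (standard error 0.20). Of the 22 measured members 14 had positive and 8 negative log2 fold changes. Errfi1 was at -0.60, Cic at -0.54, Ets2 at -0.53 and Dusp6 at -0.02. Among 15 measured FGF ligands and receptors none was called in either way (median 0.01, adjusted p = 0.911). Fgf7 had a log2 fold change of 1.53 (standard error 0.59, adjusted p = 0.329) and Fgfrl1 of -0.46. In the Wnt list Lef1 rose, over all genes and adjusted over the list alone, and the other 19 measured members did not pass (median 0.03, adjusted p = 0.375). Wnt4 and Nkd2 had log2 fold changes of 1.23 (adjusted p = 0.256) and 0.76 (adjusted p = 0.267). No hedgehog target was called among 12 measured (median -0.20, adjusted p = 0.348), with Ptch1 at -0.63 (adjusted p = 0.221) and Gli1 at -1.08 (adjusted p = 0.401). With each library left out in turn the hedgehog median ran from -0.29 to -0.10, Ptch1 from -0.80 to -0.36 and Gli1 from -1.50 to -0.48. After GC correction the hedgehog median was 0.03. No BMP and TGF-beta pathway gene was called among 28 (median -0.05, adjusted p = 0.772), with Chrdl1 at -0.51 and Bmp5 at 0.58. Neither list had a member past the threshold adjusted over the list alone. Of 26 measured human craniosynostosis genes Esco2 rose, over all genes and adjusted over the list alone, and 25 did not pass (median 0.01, adjusted p = 0.965), with Efnb1 at -0.69. Craniofacial patterning factors (18 measured, median 0.03, adjusted p = 0.965) had none called in either way, with Alx1 at 0.41, Eya1 at 0.31 and Six2 at -0.47. With each library left out in turn Six2 ran from -0.89 to -0.28, with edgeR adjusted p from 0.00846 to 0.737. For the BMP, hypertrophy, craniosynostosis, patterning and protease lists the median, the mean and the direction of the test differed in sign.

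**Figure D2:**
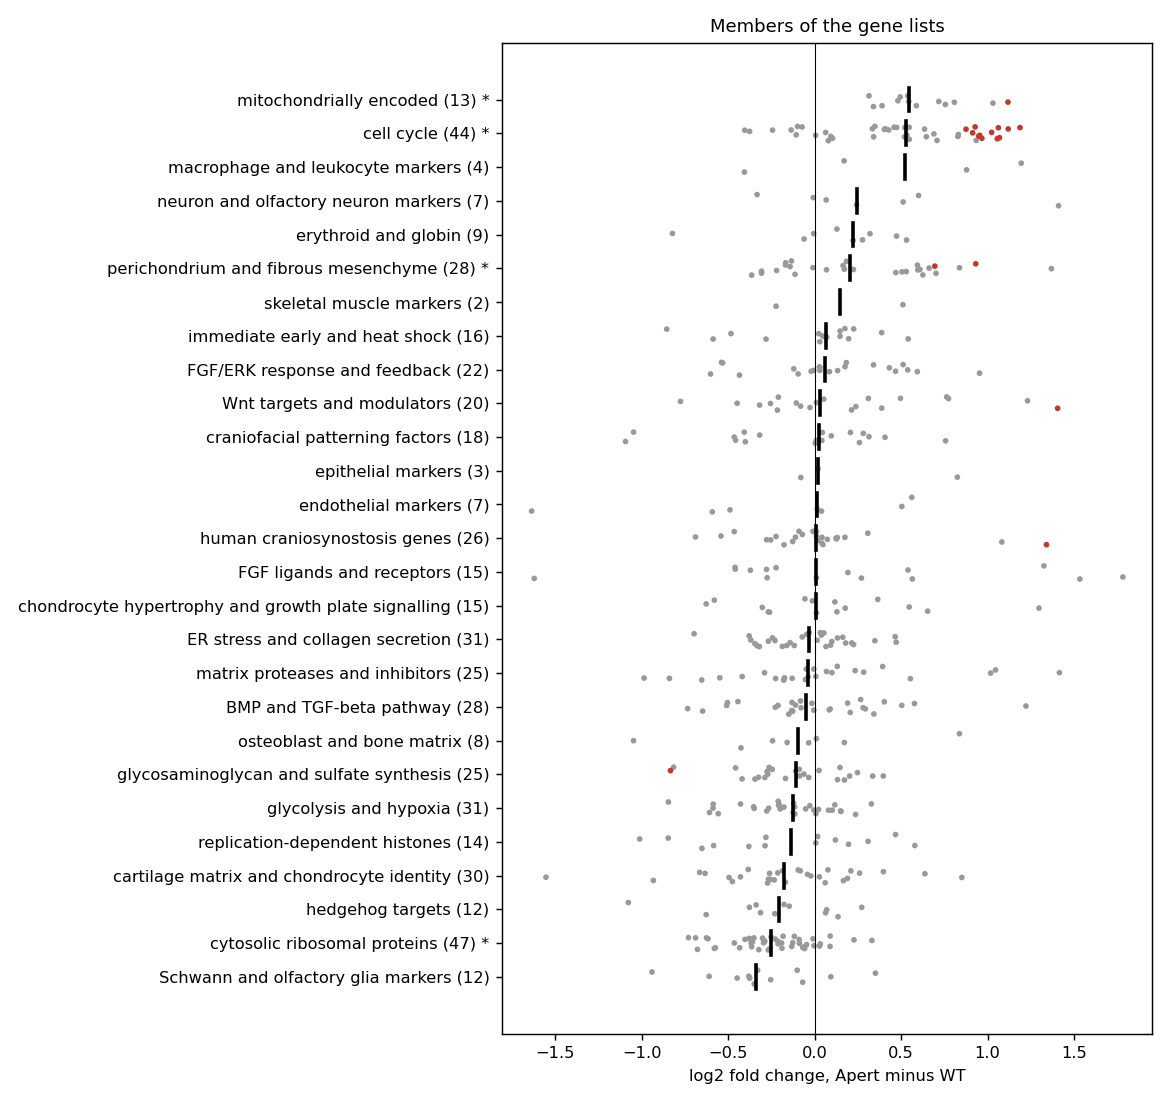
Log2 fold change (x axis, Apert minus WT) of every measured member of 27 gene lists (y axis, number measured in parentheses). Each point is a gene, red points passed the gene test, the black bar is the list median and an asterisk marks a list past the camera test with a preset correlation. The cell cycle and mitochondrially encoded lists have medians of 0.53 and 0.54, the fibrous list 0.20 and the ribosomal protein list -0.25, and the other 23 lists, with medians from -0.34 to 0.52, did not pass.

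Apart from the perichondrium and fibrous mesenchyme list above, markers of other cell types that a captured region could hold did not pass as lists, and none of their genes was called. Schwann and olfactory glia markers had a median log2 fold change of -0.34 over 12 measured genes (camera, adjusted p = 0.157). Sox10 was at 145 ± 25.2 CPM in WT and 94.7 ± 15.9 CPM in Apert (SD, n = 3 each; adjusted p = 0.138), and adjusted over the list alone 1 gene was lower. Neuron and olfactory neuron markers (7 measured of 24, median 0.24, adjusted p = 0.372) and endothelial markers (7 of 22, median 0.01, adjusted p = 0.772; Eng 0.50, Sox18 -1.64) had no member past the threshold adjusted over the list alone. The same held for macrophage and leukocyte markers (4 of 23, median 0.52, adjusted p = 0.772; Cd68 0.88) and epithelial markers (3 of 24, median 0.02, adjusted p = 0.502). Skeletal muscle markers (2 of 24 measured, median 0.14, adjusted p = 0.619) had 1 higher adjusted over the list alone, Neb, at 20.3 ± 3.06 CPM in WT and 29.0 ± 2.53 CPM in Apert. With no expression filter this list passed at the preset correlation (adjusted p = 0.0418; 0.894 with an estimated correlation and the filter). Erythroid and globin genes (9 measured, median 0.22, adjusted p = 0.375) had none past the threshold adjusted over the list alone, with Tfrc at 0.53 and Hba-x at -0.82. They passed at the preset correlation without WT replicate 2 (median 0.74, adjusted p = 0.0234; 0.894 with an estimated correlation in all libraries), while the median was -0.08 without WT replicate 1 (adjusted p = 0.980), 0.02 without Apert replicate 1 and 0.12 without Apert replicate 3. With each library left out in turn, medians ran from -0.39 to -0.15 for the glia list, 0.06 to 0.23 for the neuron list, -0.43 to 0.09 for the endothelial list, -0.14 to 1.11 for the macrophage list, -0.21 to 0.49 for the epithelial list and -0.04 to 0.28 for the muscle list, and none of these passed. For the endothelial list the median was above 0, the mean was -0.23 and the test pointed down.

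The lists of mitochondrially encoded and cytosolic ribosomal protein genes passed camera at its preset correlation in opposite directions, although 1 of 13 and 0 of 47 genes were called. All 13 mitochondrially encoded protein genes had positive log2 fold changes. The gene mt-Co2, a cytochrome oxidase subunit gene, rose from 23.9 ± 5.42 to 51.9 ± 6.07 CPM (SD, n = 3 each; adjusted p = 0.0215), and 9 genes rose and none fell adjusted over the list alone. The list median was 0.54 (camera, adjusted p = 9.79e-09; adjusted p = 0.736 with an estimated correlation). List means were -0.06, -0.51 and -0.36 in WT replicates 1 to 3 and 0.39, 0.44 and 0.10 in Apert replicates 1 to 3 (exact permutation p = 0.1, and 0.2 after GC correction). The electron transport genes mt-Nd5 (5550.3 ± 778 and 8089.8 ± 828 CPM, adjusted p = 0.0955) and mt-Nd2 (1739 ± 420.1 and 2859 ± 362 CPM, adjusted p = 0.0599) did not pass. Nuclear copies of mitochondrial DNA make these counts uncertain, and mt-Nd5 shares exons with mt-Nd6. The mitochondrial genome, mostly its ribosomal RNA, took 29.6% ± 0.756 of counts in WT and 37.1% ± 3.06 in Apert (SD, n = 3 each; exact permutation p = 0.1). Gm42418, a locus that collects ribosomal RNA reads, took 3.02% ± 1.36 and 1.19% ± 0.506 (exact permutation p = 0.1). None of the 47 ribosomal protein genes was called, 4 were lower adjusted over the list alone, and the median was -0.25 (camera, adjusted p = 7.29e-05; adjusted p = 0.890 with an estimated correlation). List means overlapped, at 0.21, 0.23 and -0.06 in WT replicates 1 to 3 and 0.10, -0.41 and -0.08 in Apert replicates 1 to 3 (exact permutation p = 0.2). Rpl10 was at 259 ± 24.8 CPM in WT and 156 ± 35.6 CPM in Apert (SD, n = 3 each; adjusted p = 0.0561) and Rps3 at a log2 fold change of -0.69 (adjusted p = 0.0955). Ribosomal protein genes have many near-identical processed copies and are uncertain. Without Apert replicate 2 the ribosomal protein list did not pass (median -0.14, adjusted p = 0.490). After correction for GC content the medians of the mitochondrial and ribosomal protein lists were 0.29 and -0.14 (adjusted p = 5.78e-04 and 0.00640, and 0.763 and 0.893 with an estimated correlation).

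Glycolysis and hypoxia genes (31 measured) had none called, over all genes or adjusted over the list alone, and a median of -0.13 (camera, adjusted p = 0.240). Gapdh was at 538 ± 113 CPM in WT and 399.6 ± 91.1 CPM in Apert (SD, n = 3 each; adjusted p = 0.351). This list passed at the preset correlation without Apert replicate 1 (median -0.28, adjusted p = 0.0122; 0.892 with an estimated correlation in all libraries), and without Apert replicate 3 its median was -0.05 (adjusted p = 0.872). Replication-dependent histone genes (14 measured, median -0.14, adjusted p = 0.911) and immediate early and heat shock genes (16 measured, median 0.07, adjusted p = 0.945; Hsp90aa1 0.39) had none called in either way. The mean of the latter list was -0.01. With each library left out in turn the histone median ran from -0.54 to 0.37, and after GC correction it was 0.09.

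Fold changes were related to the GC content of the genes. Over the tested genes with a GC value, Spearman's rho between log2 fold change and GC content was -0.411 across genes, which are not independent replicates. The median log2 fold change went from 0.23 in the 1320 genes lowest in GC to -0.30 in the 1319 highest. The genes that rose had a median GC content of 41.8%, those that fell 53.1% and all tested genes 48.9%. Within single libraries, rho between deviation from the gene mean and GC content was 0.234, 0.425 and 0.0286 in WT replicates 1 to 3 and -0.172, -0.236 and -0.182 in Apert replicates 1 to 3 (exact permutation p = 0.1, the smallest possible). Gene length showed rho of 0.00645 with log2 fold change.

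**Figure D3:**
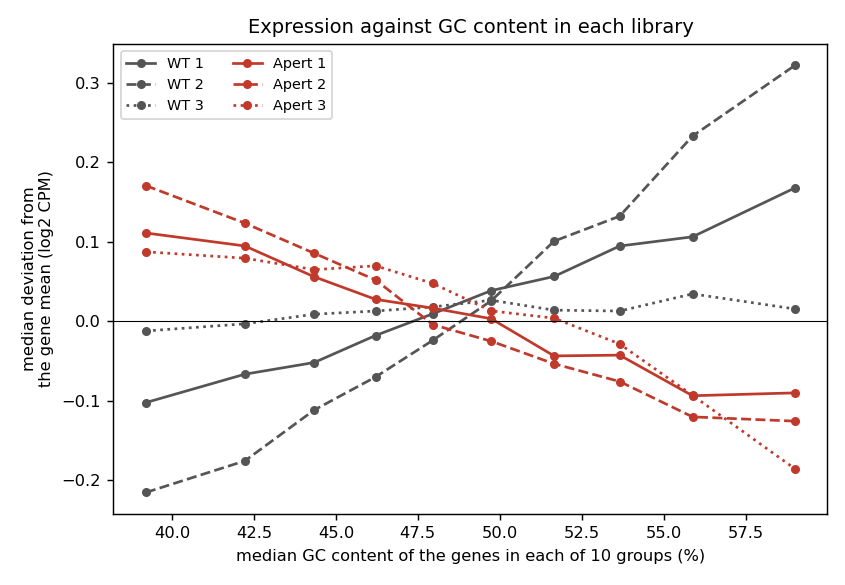
Median deviation of log2 CPM from the mean of all 6 libraries (y axis) for 10 equal groups of genes ordered by GC content (x axis, median GC content of each group in percent), with 1 line per library, WT in grey and Apert in red. All 3 Apert libraries slope down; WT replicates 1 and 2 slope up and WT replicate 3 is close to flat, from -0.01 in the lowest group to 0.02 in the highest.

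A knock-in allele can carry neighbouring DNA of another strain, so genes near Fgfr2 were compared with all others. Within 10 Mb of the gene, 2 of 207 tested genes were called, Mki67 (135689788 to 135716379 on chromosome 7) and H19 (142575529 to 142578143 on the same chromosome). Distances were counted from both listed ends of Fgfr2, of which the upper, reached across the exons shared with Ctbp2, is a doubtful end of the gene model. H19 lies further than 10 Mb from the lower end, so its place among the near genes, and the 207, rest on that upper end. Elsewhere 58 of 13126 were called (two-sided Fisher's exact test, p = 0.239). At an unadjusted p below 0.05 the shares were 9.18% near Fgfr2 and 11.4% elsewhere (Fisher's exact test, p = 0.377).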

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

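The corrections for GC content and length, the block combined with GC correction, and the leave-one-out counts after GC correction were chosen after the data were seen. Where a count or call changed below, the cause was not tested unless stated.

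The count of 60 genes stayed between 53 and 75 with RLE or upper-quartile scaling, a filter of 1 CPM, removal of globin, mitochondrial and ribosomal RNA genes, thinned counts, length correction, robust edgeR, limma-voom, and X and Y genes left out. Falls numbered 13 in thinned counts and 12 with robust edgeR. Scaling by library totals gave 17 rises and 24 falls, with 24 of the 41 genes shared with the 60, and shifts all folds by construction. No filter gave 247 genes (154 up, 93 down), DESeq2 195 (143 up, 52 down, with 59 of the 60) and voom with quality weights 104 (89 up, 15 down). In the simulated data 9.10% of DESeq2 calls were unchanged genes, beside 5.21% of edgeR calls. An adjusted p below 0.10 gave 129 (105 up, 24 down) and a log2 fold change of at least 1 in size 38 (33 up), by construction. GC correction gave 5 genes (4 up, 1 down), and GC with length correction 7 (6 up, 1 down), all among the 60.

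With the replicate number as a block, 172 genes passed (128 up, 44 down), including all 60, and with the block and GC correction 74, of which 11 fell and 41 were among the 60. The labels do not pair the numbers. Deviations from the group means correlated at 0.194, 0.0196 and 0.0860 for libraries with equal numbers, and WT replicate 2 correlated most with Apert replicate 3 (0.0418), so the numbers were not taken as pairs. The 4 lists that passed at camera's preset correlation also did so with the block, and none passed with an estimated correlation (0.736 to 0.890, without the block).

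With each library left out in turn, calls ran from 0 (without WT replicate 3) to 229 (without Apert replicate 1), rises from 0 to 119 and falls from 0 to 110. At 0 calls, edgeR gave 1376 genes with an unadjusted p below 0.05. After GC correction the range was 0 to 44: without WT replicates 1, 2 and 3, 0, 14 and 0 genes, and without Apert replicates 1, 2 and 3, 44, 0, 0. The unadjusted edgeR counts for the 4 zeros ran from 791 to 1005.

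The lists of cell cycle, mitochondrially encoded, ribosomal protein and fibrous mesenchyme genes passed camera at its preset correlation under every scaling, filter, block and GC or length setting in which they were tested. With an estimated correlation camera called 0 lists (adjusted p = 0.736, 0.736, 0.890 and 0.736 in that order), with 0 lists at an unadjusted p below 0.05. The fry test called 0 (0.218, 0.151, 0.577 and 0.267), with 6 lists below 0.05 unadjusted. These tests allow for correlation between members by construction, but that is not all that changes. For the FGF/ERK list the estimated correlation was -0.0373, below the preset 0.01. Its unadjusted camera p still went from 0.160 at the preset correlation to 0.197 with the estimated one. Leaving out libraries, 3 to 5 lists passed. The ribosomal protein list had adjusted p of 3.73e-07 to 0.490 (not passing without Apert replicate 2) and the fibrous list 0.00293 to 0.217 (not passing without WT replicate 3, Apert replicate 1 or Apert replicate 3). The cell cycle list passed each time (6.68e-18 to 5.55e-07), as did the mitochondrial list (1.59e-10 to 2.85e-05).

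Of 43 called genes followed across the settings, none reversed in any setting. Of these, 5 were called after GC correction, 23 with scaling by library totals and 42 with DESeq2. Of 83 other genes that did not pass, 20 passed with no filter, 19 without Apert replicate 1 (Sox9 and Postn among them), 15 with the block and 13 of 73 with DESeq2. Igf2 was not called (log2 fold change -0.14) and had 0.077 after GC correction, 0.0808 after GC and length correction and 0.0711 with the block and GC correction. The share of counts on globin genes differed by -0.000966 percentage points (Apert minus WT), with a range of -0.00174 to 0.000297, positive without WT replicate 2. Fgfr2 did not pass in any setting (leave-one-out range -0.40 to -0.20) and neither did the test of called genes near it. Sex was not entered as a covariate, since all libraries had Xist counts and no counts on the listed Y genes. In the self-test, edgeR found 46.1% of genes changed 2-fold and 8.49% of those changed 1.5-fold, so at this depth and spread most smaller changes would go uncalled.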

Other observations

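The GC tests, the test of perichondrial tissue, the comparison of mitosis with DNA replication genes, the test without called genes and the gene lists first named here were chosen after the results were seen; the depth test and the 10 splits were not, although the GC correction inside the last split count was.

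The condensin core genes Smc4 and Smc2 rose from 162 ± 18.5 to 317 ± 16.4 CPM (adjusted p = 0.00453) and from 96.8 ± 16.0 to 181 ± 26.5 CPM (adjusted p = 0.0209). The kinetochore genes Knl1 (67.1 ± 15.1 to 153 ± 14.2 CPM) and Spc25 (13.04 ± 1.88 to 28.6 ± 6.03 CPM) rose as well (SD, n = 3 each). Of 43 condensin, cohesin and kinetochore genes, 7 rose, none fell and 36 did not pass, with a median log2 fold change of 0.61, and 0.54 after GC correction. This list was written after the called genes were seen, so these are values and no test of the list is given.

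Cntnap2 went from 12.98 ± 3.46 to 28.4 ± 5.39 CPM (adjusted p = 0.0485) and Ctnnd2 from 39.0 ± 10.4 to 76.2 ± 4.73 CPM (SD, n = 3 each; adjusted p = 0.0363). Among 26 measured semaphorins, plexins and neuropilins, a list also written after Sema3e and Sema3a were seen to rise, those 2 rose and 24 did not pass, and adjusted over the list alone 5 were higher and 2 lower. Of the 26, 16 had negative log2 fold changes and the median was -0.10 (camera, adjusted p = 0.988). Sema3c (log2 fold change 0.53, adjusted p = 0.138), Sema5b (1.84, adjusted p = 0.0630) and Plxna4 (-1.04, adjusted p = 0.193) did not pass. H19 fell while Igf2, its neighbour in the same imprinted domain, had a log2 fold change of -0.14 (adjusted p = 0.749). Of 25 measured imprinted genes only H19 was called (median 0.00, camera adjusted p = 0.629), and Plagl1 was at 0.44 (adjusted p = 0.254). Calm2 (267 ± 11.7 to 444 ± 34.9 CPM) and Hmga2 (495 ± 64.7 to 844 ± 194 CPM) rose.

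The cell cycle list had a median log2 fold change of 0.53 (bootstrap SE 0.11 after GC correction, 0.08 in thinned counts). Each SE in this paragraph resamples genes, which are correlated, and does not measure the spread between libraries or animals. A GC-dependent difference between libraries as its whole cause is argued against by the median of 0.51 after GC correction. In counts thinned to one total the median was 0.55. Fold changes are scaled by library totals with or without thinning, so this value does not decide on lower depth of the Apert libraries. More perichondrial tissue in the Apert captures cannot be told apart from a change within the cartilage. The fibrous median lay below the cell cycle median by a difference of -0.32 (SE 0.19; -0.40 for the fibrous members of low baseline), but of the 10 most abundant fibrous genes, Col3a1 rose by at least the cell cycle median and Postn (0.60, adjusted p = 0.254; 0.19 without Apert replicate 3) and Prrx1 (0.53, adjusted p = 0.120; 0.40 without Apert replicate 1) had folds as large, while Col1a2 (0.17) and Col12a1 (0.22) did not, and 3 of the 28 fibrous members are in another list. More dividing cells in Apert cartilage may be the source of the rise but were not tested apart from tissue composition, and a difference in RNA quality stays open too, since the mitochondrial share of counts (29.6% in WT, 37.1% in Apert) and the number of detected genes separate the genotypes in every library.

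Within the cell cycle list, 12 of 24 mitosis genes rose (median 0.85) and 0 of 20 DNA replication genes passed in edgeR or adjusted over the list alone (5 at an unadjusted p below 0.05; median 0.09), with Mcm2 at -0.38 and Rrm1 at 0.52. The mean of mitosis minus replication genes was -0.31, -0.30 and -0.33 in WT replicates 1 to 3 and 0.16, 0.27 and 0.51 in Apert replicates 1 to 3 (exact permutation p = 0.1, the smallest possible). Both parts were set after the results were seen, so this p is no independent support. The difference of the medians was 0.77 and, after GC correction, 0.65 (SE 0.08), which argues against a GC-dependent difference as the whole cause. This SE resamples genes, whose estimated correlation was 0.53 in the mitosis part and 0.40 in the replication part. It does not measure the spread between libraries or animals. A candidate explanation is a larger share of Apert cells in or near mitosis, which was not tested, and differences in captured tissue or RNA quality stay open here too.

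Low-GC genes were higher in Apert libraries (rho of -0.411 across genes). Without the 92 called or cell cycle genes rho was -0.407, so the trend was present among the other genes. Removing so few of the 13333 tested genes can hardly move a rank correlation, so no conclusion about an explanation is drawn from it. The WT libraries differed from each other in rho by up to 0.397 (0.0286 to 0.425), beside 0.426 between the genotype means. The Apert libraries lay close together, from -0.236 to -0.172. A GC-dependent step of amplification or sequencing that varied between libraries may be the source of the trend, but only the WT libraries show such variation within a genotype. Genotype is not excluded as a contributor, since all 3 Apert values lay below all 3 WT values. This trend is the reason that the count of 5 genes after GC correction stands beside that of 60.

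Splitting the 6 libraries 3 against 3 can be done in 10 ways, so the share of splits as large as the real split cannot be under 0.1. In edgeR 1 split, the real one, gave as many genes (60; highest other 0, with up to 1193 genes at an unadjusted p below 0.05), and after GC correction 1 split gave as many (5; highest other 0, with up to 1171 unadjusted). The real split itself had 1000 unadjusted genes after GC correction, so by this count it was not the largest. Setting WT replicates 1 and 2 with Apert replicate 1 gave the 1171. Setting WT replicates 1 and 3 with Apert replicate 1 gave 1155. In 4 splits as many lists passed camera as in the real one (4; highest other 8), and 1 split had a cell cycle median as far from 0 (0.53; highest other 0.42). The split with 1193 unadjusted genes sets WT replicates 1 and 2 and Apert replicate 1, the 3 libraries with the most counts, against the 3 with the fewest; it gave 0 genes after adjustment in edgeR and 6 lists. Beside the 1515 unadjusted genes of the real split, this points to a structure of the libraries other than genotype. The first principal component, with 30.0% of the variance, has Apert replicates 2 and 3 at 42.1 and 35.05 and the other 4 libraries between -31.3 and -5.29. With counts thinned to a common total the real split gave 67 genes, 53 of them among the 60.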
